A study of Pimephales promelas with 16 samples.

How the data were processed

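RNA from the livers and gonads of male fathead minnows (*Pimephales promelas*, a small North American fish used in toxicology) was measured on 16 two-colour oligonucleotide microarrays of 60-base probes, with 4 arrays for each combination of tissue and water. Per the labels' protocols, total RNA was extracted, amplified and labelled as cRNA, with the fish RNA in the dye Cy5 and a common reference in the dye Cy3 on every array. The reference was, per the series' design text, made of equal amounts of liver, brain and gonad RNA from control females and males. No dye swap was made, so any dye bias of a probe is shared by all arrays and cancels in the differences between groups. The series' design text speaks of ovarian samples in Cy5, while every sample label says male and gonad, and the labels were followed here.

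The slides were scanned and their spots measured with Agilent Feature Extraction, version 9.5 per the submitters' processing notes and 9.5.1.1 per the file headers. Per the file headers, each scanner file holds the mean intensity and the local background intensity of 44407 spots in each channel, both on a linear scale and not normalized, with flags for saturation, for uneven spots or uneven local background, and for signal well above background. Each file also holds the scanner software's own log10 ratio of Cy5 over Cy3. The authors' deposited value table, also a log10 ratio, held the scanner software's log ratio rounded, with a largest difference of 0.005, so its direction and scale were settled. Its column medians were 0 on 15 arrays and -0.203 on liver effluent array 1. The gene or contig name of a probe was taken from the scanner files as they gave it. Of 21495 probes, 35 carried a gene name, for 34 different genes, and all others carried only an identifier of an expressed sequence or contig. GenBank accessions stood in the names of 6937 probes, and 0 of them were found in the reference gene table (assembly fPimPro1.hap1.1), so these probes stayed without a gene name. No probe position in a genome was known, since no genome sequence was used here.

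Background was corrected with the normexp convolution model (offset 50), ratios were normalized within each array by loess with control spots at weight 0, and the 2 spots of a probe were averaged, all in limma 3.58.1 under R 4.3.3 with data.table version 1.17.8. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15. Spots flagged as uneven in either channel, 64 to 490 per array, were left out before the background model was fitted. This order was chosen from the fitted background parameters, after the number of called probes under the default order had been seen. With the flagged spots kept in the fit, a few spots with bright local background pulled the fitted Cy5 background mean of an array down to as low as -1119, and without them the means lay between -11.0 and 14.2 on all 16 arrays. The default order was kept as an alternative. No step was taken between arrays.

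Probes well above background in Cy5 on at least 4 arrays of a comparison were tested with limma's linear model and moderated statistics (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over all probes of a comparison. A probe was called at an adjusted p under 0.05. The comparisons were effluent against control water in liver, the same in gonad, control gonad against control liver, and the difference of the effluent effect between liver and gonad over all 16 arrays. The comparisons, a first set of alternatives and the rule for naming genes were fixed before the data were examined. The order in which uneven spots were left out and further alternatives were chosen later. For each effluent comparison that rule named up to 12 genes in each direction, the largest changes among probes with a gene name that were called and whose groups did not overlap. Any remainder was to be taken by the unadjusted p among non-overlapping genes with a log2 change of at least 1, and 0 genes met this. For the tissues it named the 5 largest in each direction. It always named measured probes of vitellogenin, egg coat proteins, estrogen and androgen receptors, and other listed exposure markers, and up to 4 members of each gene list with the smallest p. One probe per gene was used, the brightest over all arrays. Probes without a gene name, and alpha-amylase and pentraxin, were singled out after their values had been seen. At most 2 unnamed probes per direction are given by identifier in each comparison. In gonad the cluster mate of the called probe was preferred to the probe with the next smallest p among those higher after effluent, which did not pass and had 1 effluent array apart from the rest. A planned comparison of vitellogenin, the egg yolk precursor, was not made because 0 probes carried that name.

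A set of 27 gene lists was fixed in advance, covering egg proteins, xenobiotic metabolism, stress defence, steroid hormones, germ cells, lipid metabolism, plasma proteins and markers of other tissues. Only 7 lists matched any of the gene names on the array, through 9 names, and none had the 5 measured genes set as the minimum for a set test (camera and fry), so no set test was run. Calls adjusted over the list alone are reported in their place.

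The headers gave the slide, the position on the slide and the scan day of each array. The 16 arrays lay on 4 slides of 4 positions. Each slide held 1 array of each group, each group lay once in each position, and 1 of the 4 slides was scanned on another day. The slide number coincided with the replicate number. Slide and position were each added to the model as fixed blocks. The replicate block was a fixed factor too in the effluent comparisons, where it equals the slide block. Between the tissues and for the difference of the effluent effect it was instead the number within a treatment, with a common correlation from duplicateCorrelation of limma, since both tissues of a fish may carry 1 number. The design text states that the replicates were different fish, but the tank and the exposure run of each fish, and whether liver and gonad samples shared fish, were not given in the sources used here. Not all control and effluent samples of the same number deviated together within a tissue, so the numbers were not used to pair samples.

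Where a probe was not well above background in Cy5 on any array of a group, its level there is only an upper limit, and this is said beside the fitted difference. The number of arrays limits the precision. In simulated data built on the real arrays with 200 changed probes, the gonad model recovered 41.8% of probes changed by 1 log2 unit, 83.6% of those changed by 2 and 92.4% of those changed by 3 among 15774 probes. The liver model without liver effluent array 1 recovered 22.4%, 61.2% and 86.4% among 12848 probes, and with that array 0%, 7.46% and 4.55% among 12880 probes. The tissue model recovered 40.3%, 82.1% and 92.4% among 15311 probes, and the model of the difference between tissues 25.4%, 71.6% and 87.9% among 16575 probes. Unchanged probes called numbered 10 in gonad, 5 and 0 in liver without and with that array, 9 between tissues and 9 for the difference. The real tissue comparison called 9642 probes, far more than the 200 simulated changes, so its adjusted threshold was less strict. The simulated tissue shares therefore do not carry over to it. The real effluent comparisons called 0 probes in liver and 1 in gonad, and the difference between tissues 0, so their adjusted threshold was stricter. The simulated shares may therefore be too high for them.

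Alternatives covered the background correction, the normalization, the Cy5 channel alone, the deposited table, the filter on dim probes, the arrays in the fit, the moderation, array weights, replicate, slide and position blocks, and leaving out each array in turn. Liver effluent array 1 had almost no Cy5 signal. It was kept in the main comparisons. Leaving out each array in turn, this one included, was planned, and combining its absence with another choice was decided after seeing the data.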

Results

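Adult male fathead minnows about 6 months old were exposed for 3 weeks to undiluted effluent of a wastewater treatment plant or to well water, and their liver and gonad transcripts were compared. Water was delivered at 400 ml/min for 4 hours, 2 times a day, at 25 °C, to tanks of 9 males and 3 females, in 2 runs. The 4 groups, control liver, effluent liver, control gonad and effluent gonad, had 4 arrays each, from different fish within a group. Fish of one tank shared their water, and the tank of each fish was not given, so the p-values measure the spread between fish and cannot separate effluent from tank.

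In gonad, 14783 to 16496 of the 21495 probes were well above background in the Cy5 channel of the fish RNA (8 arrays). In liver the range was 11238 to 14312 on 7 arrays, while liver effluent array 1 had 1411. The Cy3 channel of the reference was well above background for 13645 to 15485 probes on all 16 arrays. On liver effluent array 1 the labelled spike-in control had a mean Cy5 signal of 72.3, against 7009 to 33217 on the other 15 arrays, and negative control spots lay between 67.6 and 132. Log ratios correlated across probes with Pearson's r of 0.773 to 0.944 among gonad arrays, 0.825 to 0.914 among the 7 other liver arrays and 0.148 to 0.339 between the tissues, and those of liver effluent array 1 correlated with the others at -0.039 to -0.006. Liver results are therefore given with and without this array.

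**Figure D1:**
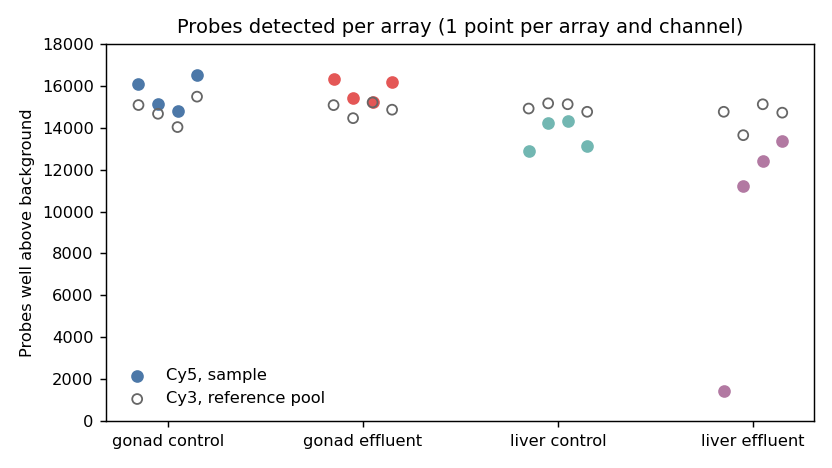
Number of probes well above background on each of the 16 arrays, by group, in the Cy5 channel (filled, fish RNA) and the Cy3 channel (open, reference pool). Liver effluent array 1 had 1411 probes in Cy5, and the other 15 arrays had 11238 to 16496.

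The control fish gave the background of transcripts that differ between the tissues. Control gonads had higher levels of inhibin, a gonadal protein that restrains follicle-stimulating hormone, of cyclin B1, which drives entry into mitosis and meiosis, and of the adhesion protein cadherin 17. Control livers had higher levels of complement C3S, a plasma protein of innate immunity made in liver, of estrogen receptor alpha, of CD 18 type 2, a leukocyte integrin chain, and of the mitochondrial gene cytochrome b. Inhibin differed by 2.27 ± 0.19 (SE, n = 4 per group, log2) and cyclin B1 by 2.205 ± 0.18, with limma adjusted p of 1.22e-05 and 9.4e-06. Inhibin was not well above background on any control liver array, so its liver level is only an upper limit. Cadherin 17 was 2.08 ± 0.26 higher in gonad, with a limma adjusted p of 0.00014. Complement C3S lay at -3.79 ± 0.51 in gonad relative to liver, estrogen receptor alpha at -2.44 ± 0.36, CD 18 type 2 at -1.41 ± 0.15 and cytochrome b at -1.28 ± 0.18, with limma adjusted p from 4.6e-05 to 0.00038. In each of these 7 genes all 4 gonads lay on one side of all 4 livers, and the difference had the same sign on all 4 slides.

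Smaller differences were seen for further named genes. Follistatin, which binds activin, was 0.68 ± 0.20 higher in gonad (limma adjusted p = 0.017). The receptor of follicle-stimulating hormone, FSHR, was 0.56 ± 0.14 higher (limma adjusted p = 0.0069) and was not well above background on any control liver array either. Inhibin beta b was above background on 3 of 4 control gonads and on 0 control livers, and it entered no test between the tissues. In liver, 149D2R (-0.96 ± 0.15 in gonad relative to liver), myocyte enhancer factor 2a (-0.73 ± 0.13) and the activin receptor ACTRIIB (-0.50 ± 0.13) were higher, each with a limma adjusted p under 0.05. Pentraxin was 1.64 ± 0.63 higher in gonad with a limma adjusted p of 0.046, and its groups overlapped. Under median centring in place of loess, 149D2R, ACTRIIB and FSHR no longer passed the threshold, and with uneven spots kept in the background fit ACTRIIB and pentraxin did not. Pentraxin also fell short of it with no filter on dim probes and without any one of 6 arrays (gonad control 1, 3 or 4, or liver control 1, 2 or 3). Alpha-amylase, a digestive enzyme of the exocrine pancreas, lay at -2.93 ± 1.15 in gonad and did not pass, with a limma adjusted p of 0.051 and control livers spread from -2.19 to 4.00. It passed under 12 of 23 alternatives, the slide, position and replicate blocks among them, with limma adjusted p from 0.000979 to 0.124 over all 23, and without liver control 2 the difference was -4.13. Zona pellucida glycoprotein 3 (ZP3), an egg coat protein, differed by 0.05 ± 0.28, and both tissues lay far below the reference pool, at -5.66 ± 0.32 (SD, n = 4) in control gonad and -5.71 ± 0.54 in control liver.

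Of the 19 named genes tested between the tissues, 13 were called, 6 higher in gonad and 7 higher in liver. Adjusted over the list alone, the tissue difference was called for 1 gene of the egg protein list (estrogen receptor alpha), 2 of the steroidogenesis and gonadal hormone list (inhibin and FSHR), and 1 each of the plasma protein list (complement C3S), the cell cycle list (cyclin B1) and the somatic gonad marker list (FSHR), while the oocyte list (ZP3) had 0 and the single matched gene of the immune list was not measured. Over all probes, 9642 of 15359 were called, 4963 higher in gonad and 4679 higher in liver, and 6222 of them differed by at least 1 log2 unit. With the slide as a block 9469 probes were called, and with the position on the slide 8823. Median centring, which moved the median of all probes by 0.55 log2 units towards gonad, gave 7225 probes higher in gonad and 2411 higher in liver.

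**Figure D2:**
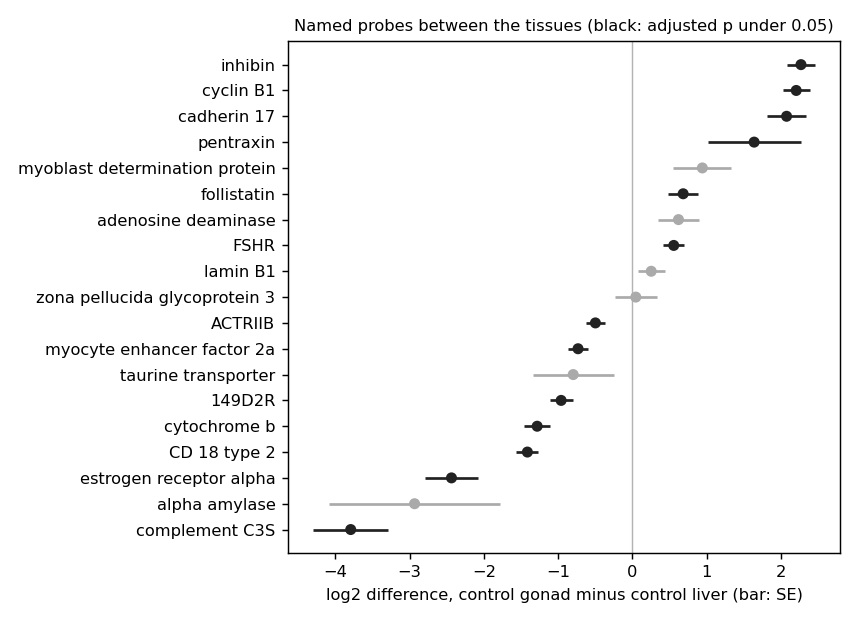
Difference of the log2 ratio between control gonad and control liver for the 19 named genes tested (points, with the SE of the limma model as bars, n = 4 arrays per group). Black marks the 13 genes with an adjusted p under 0.05, from inhibin at 2.27 to complement C3S at -3.79.

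The question of the series was what the effluent did in male tissues. In gonad, 1 probe of 15827 was called after effluent exposure, and it carried no gene name. This probe, EA_Pp_61804, was 3.195 ± 0.18 (SE, n = 4 per group, log2) higher in effluent gonads, a 9.16-fold difference, with a limma adjusted p of 0.00085. Its log2 ratio was -1.47 ± 0.17 (SD, n = 4) in control gonads and 1.72 ± 0.29 in effluent gonads, all 4 effluent arrays lay above all 4 controls, and the difference within a slide ran from 2.97 to 3.43. Its 60-base sequence is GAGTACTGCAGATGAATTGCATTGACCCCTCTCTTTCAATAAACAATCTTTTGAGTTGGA. The files place it in a cluster of contigs with 1 other probe, EA_Pp_63029 (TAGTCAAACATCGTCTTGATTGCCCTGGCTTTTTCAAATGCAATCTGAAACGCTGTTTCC), which was 1.14 ± 0.20 higher in effluent gonads on all 4 slides and did not pass, with a limma adjusted p of 0.91. EA_Pp_63029 was not well above background on gonad controls 1, 2 and 3, so its level there is only an upper limit. With the slide as a block the call of EA_Pp_61804 held (3.195 ± 0.16, limma adjusted p = 0.033). With the position on the slide it was lost (3.195 ± 0.20, limma adjusted p = 0.107). Each group lay once in each position, so that block could not move the difference. Like the slide block, it left fewer degrees of freedom to estimate the spread. How much of the loss came from this was not tested. Over all alternatives the limma adjusted p of EA_Pp_61804 ran from 0.00035 to 0.107. With position as a block 0 probes were called in limma, and 415 had an unadjusted p under 0.05.

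None of the 19 named genes tested in gonad passed, and none of the calls adjusted over a list alone did. Inhibin lay at -0.66 ± 0.32 after effluent (log2, SE), FSHR at -0.30 ± 0.15 and complement C3S at -0.58 ± 0.29 (3 effluent arrays), each with a limma adjusted p of 1.00. All 4 effluent gonads had lower FSHR values than all 4 controls, which was so for 1 of the 19 genes, where chance gives 2.86% per gene. FSHR was well above background on 4 control and 1 effluent gonads. Inhibin beta b (-0.12 ± 0.18), cyclin B1 (-0.03 ± 0.34), estrogen receptor alpha (-0.08 ± 0.14) and ZP3 (0.31 ± 0.31) differed by no more than about their error. Estrogen receptor beta was not well above background on any gonad array. Among probes lower after effluent, the smallest p was that of EA_Pp_59105 (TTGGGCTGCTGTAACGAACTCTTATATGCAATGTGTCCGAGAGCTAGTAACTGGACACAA), which lay at -2.21 ± 0.28 with a limma adjusted p of 0.17 and all 4 effluent arrays below all 4 controls. It passed with all 16 arrays in one fit (limma adjusted p = 0.0142, within a range of 0.0142 to 1.00 over its alternatives). At an unadjusted p under 0.05 there were 528 probes, fewer than the 791 that chance would give. The count of called probes was 5 without gonad effluent 4 and 2 without gonad control 1.

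**Figure D3:**
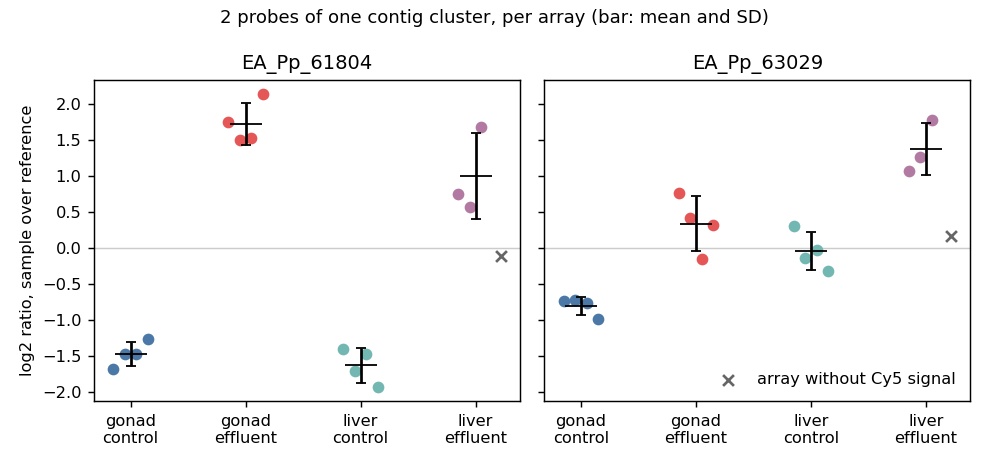
Log2 ratio of fish RNA over the reference pool on each array for the 2 probes of one contig cluster, with the mean and SD per group as bars. EA_Pp_61804 lay between 1.496 and 2.13 in effluent gonads and between -1.68 and -1.26 in control gonads, and liver effluent array 1 (cross) is left out of the mean and SD.

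In liver no probe was called after effluent exposure, with 12901 probes tested on all 8 arrays and 12867 without liver effluent array 1. In limma, an unadjusted p under 0.05 was reached by 591 and 625 probes, against 645 and 643 that chance would give. With the slide as a block limma called 0 probes with or without that array (544 and 612 at an unadjusted p under 0.05), and 0 with the position (736 and 986). Without that array the probe with the smallest p was again EA_Pp_61804, at 2.63 ± 0.30 (log2, SE, 3 effluent and 4 control livers, limma adjusted p = 0.28), and on all arrays it was 2.35 ± 0.37 (limma adjusted p = 0.86). Its ratio was -1.63 ± 0.24 (SD, n = 4) in control livers and 1.00 ± 0.60 (SD, n = 3) in effluent livers, and its cluster mate EA_Pp_63029 differed by 1.42 ± 0.24 on the same 7 arrays (limma adjusted p = 0.53). When the spread was estimated from both tissues in 1 model, EA_Pp_61804 passed in liver, with a limma adjusted p of 0.00677 on all arrays and 0.00081 without array 1, within a range of 0.00081 to 0.999 over all alternatives. It also passed in the fit of liver alone on all 8 arrays with an intensity trend and robust moderation, and so under 3 of 32 alternatives. EA_Pp_53218 (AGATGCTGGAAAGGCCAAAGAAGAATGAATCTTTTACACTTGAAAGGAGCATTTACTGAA) was 4.04 ± 0.53 higher without array 1 (limma adjusted p = 0.28) and 3.30 ± 0.78 with it. EA_Pp_61810 (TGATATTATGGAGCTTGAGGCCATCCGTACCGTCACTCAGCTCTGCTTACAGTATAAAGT) lay at -1.78 ± 0.29 without array 1 (limma adjusted p = 0.53) and -1.88 ± 0.29 with it. In the model of both tissues EA_Pp_61810 passed with and without array 1 (limma adjusted p of 0.00657 and 0.00569), and EA_Pp_53218 (0.00179) and EA_Pp_63029 (0.0412) passed without it. Over their alternatives the highest limma adjusted p of each was above 0.99. The spread in the model of both tissues came partly from the gonads. EA_Pp_61810 was well above background on no control gonad and 1 of 4 effluent gonads, where dim values can narrow that spread. EA_Pp_61804 had an SD of 0.17 and 0.29 in control and effluent gonads, against 0.24 and 0.60 in control and effluent livers. Passing in that model is therefore weaker support for a change in liver. EA_Pp_61810 was not well above background on array 1 or on liver effluent 2, so its level there is only an upper limit. Array 1 had no Cy5 signal, so its value near 0 adds no support for a fall.

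None of the 13 named genes tested in liver passed, with or without liver effluent array 1, and none did when adjusted over a list alone. Estrogen receptor alpha, whose transcript responds to estrogens in fish liver, differed by 1.01 ± 0.56 without array 1 (limma adjusted p = 0.999) and by 0.49 ± 0.66 with it. With array 1 kept, this difference of estrogen receptor alpha in liver effluent against control was 0.09 without liver control 2 and -0.01 without liver effluent 3. Array 1, without Cy5 signal, lay at -0.11 and lowered both values. These fits cannot show how much liver control 2 or liver effluent 3 carried among the other 7 livers. ZP3 differed by 0.04 ± 0.34 without array 1, complement C3S by 0.53 ± 0.53 and cyclin B1 by -0.29 ± 0.21. With array 1 these were 0.04 ± 0.37, 0.60 ± 0.48 and 0.65 ± 0.81. The ZP3 spots of array 1 were left out as uneven, so both ZP3 values rest on the same 3 effluent arrays. With array 1 kept, complement C3S in liver effluent against control was 0.25 without liver control 2, 1.09 without liver control 1 and -2.19 under median centring. Under median centring cyclin B1 in liver effluent against control was -0.64, and it was 1.02 without liver effluent 2. Array 1, kept in the latter fit, lay at 0.03 for cyclin B1, against -3.91 to -3.65 in the other effluent livers, and raised that value. ZP3 (zona pellucida glycoprotein 3 in liver effluent against control) was -0.18 without liver effluent 4 and 1.43 in the deposited table. Uneven spots were not left out of the deposited table. Array 1, with almost no Cy5 signal, could therefore enter its ZP3 value there, so the 1.43 cannot be read as a rise. Alpha-amylase lay at 4.48 ± 0.89 (SD, n = 3) in effluent livers and 1.41 ± 2.73 (SD, n = 4) in control livers, a difference of 3.07 ± 1.34 (SE) that did not pass (exact two-sided permutation p = 0.143). With array 1, itself at -0.05 and not well above background, the difference was 1.93 ± 1.52 (exact two-sided permutation p = 0.314). Alpha amylase in liver effluent against control fell to 0.73 ± 1.31 when liver control 2, the lowest control at -2.19, was left out and array 1 kept. Estrogen receptor beta was above background on 1 liver array. Changes of 2 log2 units in simulated liver data were recovered in 61.2% of cases without array 1 and in 7.46% with it, so smaller changes were often not detectable.

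For the difference of the effluent effect between liver and gonad, limma called 0 probes by the interaction term, with 16644 probes tested on 16 arrays and 16609 without liver effluent array 1. An unadjusted p under 0.05 was reached by 415 and 392 probes, against 832 and 830 by chance. Slide or position as a block left the count at 0, with 438 and 436 probes at an unadjusted p under 0.05 on all arrays. Of 21 named genes tested, none passed. The term for EA_Pp_61804, liver minus gonad, was -0.85 ± 0.41 on all arrays and -0.57 ± 0.34 without array 1 (limma adjusted p = 1.00 in each). That for EA_Pp_53218 was 3.47 ± 0.88 on all arrays (limma adjusted p = 1.00) and 4.21 ± 0.61 without array 1 (limma adjusted p = 0.125). On all arrays EA_Pp_61810 had the smallest p, with a term of -1.94 ± 0.31 (limma adjusted p = 0.254), and without array 1 it was -1.84 ± 0.30 (limma adjusted p = 0.180). This probe was well above background on 0 of 4 control and 1 of 4 effluent gonads, so its control gonad level is only an upper limit and a fall in gonad could not be seen. EA_Pp_53218 passed under 3 of 39 alternatives and EA_Pp_61810 under 1 of 37, each with a lowest limma adjusted p of 0.0246 and a highest of 1.00. Across 12502 probes the effects in liver and gonad correlated with Pearson's r of 0.185 and Spearman's rho of 0.178, and without array 1 across 12479 probes with 0.324 and 0.308. The correlation was 0.108 without liver effluent 2 and 0.121 without gonad effluent 3. Probes are not independent replicates, and whether the tissues came from the same fish was not given.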

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

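The search for an array apart from its group followed a set rule, and no test of an explanation chosen after the results were seen is part of it. An array counted as apart when its gap to the nearest of the other 3, divided by the range of the 4, was above the 95% critical value of Dixon's test, which chance gives in about 1 of 20 groups. This was so in 8 of 81 groups, where about 4.05 would arise by chance. The choice of unnamed probes, made after their values were seen, affects these totals.

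Estrogen receptor alpha had a log2 ratio of -0.30 in liver control 2, against 1.21 to 1.43 in the other control livers (gap over range 0.874). In the same array CD 18 type 2 was at 1.12 against 1.54 to 1.57 (0.921). Pentraxin was at 0.84 in liver control 4 against -1.70 to -1.29 (0.840). FSHR was at 0.85 in gonad control 3 against 0.43 to 0.50 (0.849), and cyclin B1 at -1.54 in gonad control 1 against -1.19 to -1.12 (0.833). In effluent gonads, alpha-amylase was at -0.53 in array 3 against -1.59 to -1.54 (0.955), and the taurine transporter at -0.93 in array 1 against 1.33 to 1.76 (0.840). EA_Pp_63029 was at -0.98 in gonad control 4 against -0.76 to -0.72 (0.841).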

How the results depend on the processing

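Alternatives that combine leaving out liver effluent array 1 with another choice, position blocks and uneven spots kept in the background fit were chosen after seeing the data, and the others were planned. In liver the count of 0 became 5 (1 higher, 4 lower) with all 16 arrays in one fit, 1 with an intensity trend and robust moderation, and 9 (5 higher, 4 lower) with the 15 arrays other than liver effluent 1 in one fit. It stayed at 0 to 0 when each array was left out, and 591 probes had an unadjusted p under 0.05 in limma. In gonad the count of 1 became 2 with all 16 arrays in one fit, 0 with the position block and 528 at an unadjusted p under 0.05, and ran from 1 to 5 when each array was left out (5 without gonad effluent 4, 2 without gonad control 1). Between tissues it ran from 7847 to 9143 when each array was left out and was 8230 with uneven spots kept, where EA_Pp_61804 in gonad effluent against control had a limma adjusted p of 0.00462 within its range of 0.00035 to 0.107. For the difference between tissues the count of 0 became 1 with Aquantile and scale normalization, 2 with array weights and 1 without liver effluent 1 under the filter on every array, and ran from 0 to 1 (1 without liver effluent 4).

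The correlation of effects, 0.185, was 0.255 with the scanner software's ratio, 0.253 with the deposited table, 0.118 for the 792 probes above background on every array and 0.292 with array weights, and ran from 0.108 to 0.324 when each array was left out. Without liver effluent 1 it was 0.316 with the slide block, 0.272 with position, 0.304 under the strict filter, 0.324 in one fit, 0.321 without background correction, 0.354 with the scanner's ratio, 0.353 with the deposited table, 0.325 with median centring, 0.322 with Aquantile and 0.311 for Cy5 alone. The cause was not tested. The median difference of all liver probes was -0.43 with the scanner software's ratio, -0.42 with the deposited table, 0.21 under the strict filter, -0.29 for Cy5 alone and -0.22 with median centring on all arrays.

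With the replicate block the counts were 0 in liver, 1 in gonad, 9874 between tissues and 0 for the difference, and the correlation was 0.184. Same-numbered control and effluent arrays of a tissue deviated with r from -0.319 to 0.301, and 1 of 7 pairs correlated best with its own number. For gonad and liver arrays of one treatment r ran from -0.182 to 0.328, and 5 of 7 pairs correlated best with their own number. Same-numbered arrays also lay on the same slide, so shared fish and a shared slide cannot be told apart here. No result changed direction past its threshold. Of single genes and probes, 523 of 525 values in gonad, 562 of 569 in liver, 488 of 522 between tissues and 973 of 977 for the difference kept their side of the threshold. Liver effluent array 1, with 1411 probes above background in Cy5, limited the liver comparison.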

Other observations

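The tests of explanations in this part were chosen after the results were seen. Counting other splits of the arrays was planned, but the rule for reading those counts was also written after. Alpha-amylase spread widely among livers, from -2.19 to 5.22 in log2 ratio over the 7 livers other than liver effluent 1, a 170-fold range. Over these livers 14 probes followed it with a correlation over 0.95 and a range over 4 log2 units. Other probes of such a range, with these 14 left out, had a median of 0 followers and a 95th percentile of 7.65. Leaving out probes that may follow one another can lower that percentile, so exceeding it decides nothing. All 14 were lower in control gonad than in control liver, 8 of them past the threshold.

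The median range of all probes over the 7 livers was 1.00. Ratios were already normalized within each array, so this median says little about scaling, or about background at some probes. The amylase range was 7.41 log2 units, 7.38 without background correction, 7.67 with the scanner software's ratio and 7.85 for Cy5 alone. The amylase spread therefore did not hinge on these choices. An effluent effect stayed open, with an exact two-sided permutation p of 0.143 over the 7 livers. Effluent livers 2, 3 and 4 lay at 4.73, 3.49 and 5.22, and control livers 1 to 4 at 2.97, -2.19, 0.87 and 4.00. With liver effluent 1 kept, at -0.05 without Cy5 signal, the difference of 1.93 fell to 0.73 without liver control 2. That fit cannot show how much liver control 2 carried among the 7 livers. Within slides 2, 3 and 4 the effluent liver was higher by 6.92, 2.62 and 1.21. A candidate explanation is that livers carried different amounts of pancreatic tissue, as 14 co-varying probes would allow. This is a hypothesis resting on 1 named gene, since the list of pancreas markers matched 0 names.

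Liver effluent array 1 had almost no Cy5 signal. Its spike-in spots had a mean Cy5 signal of 72.3, which argues against degraded fish RNA as the only cause, and the dimmest other array of its slide had 12867 probes above background, which argues against a failed slide or scan. Spike-in over negative control signal was 1.01, as would be seen if no Cy5-labelled target reached the array. No biological explanation was tested.

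EA_Pp_61804 was higher after effluent in gonad, and higher in liver without liver effluent 1. There it fell short of the threshold in the fit of liver alone (limma adjusted p = 0.28) and passed with both tissues in 1 fit (limma adjusted p = 0.00081). The latter fit drew its spread partly from the gonads. The Cy3 reference differed by 0.10 log2 units in gonad, the smallest difference within a slide was 2.04, the cluster mate differed by 1.14 in gonad, and the probe ranked 1 by p in liver without liver effluent 1. The values of the reference, the mate and the rank argue against the reference channel, a defect of its spots and measurement chance on the gonad arrays alone. For the spots this rests on the mate, which was not well above background on gonad controls 1, 2 and 3, where its level is only an upper limit. Each slide held 1 array of each group, so a shift shared by a slide cancels by the layout. The differences within slides show only that no single slide carried the result. The loss of the gonad call of EA_Pp_61804 with the position block came at the same difference of 3.195, which the balance of positions fixed in advance. An effect of effluent is a hypothesis, and a tank effect or fish that both tissues shared could give the same values.

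Other splits of the arrays were counted. In gonad 7 of 35 splits called as many probes as the real 1, and the highest other called 11. The split of slides 1 and 3 against 2 and 4 also called 1, and with the slide as a block the real groups gave 1. Chance cannot be excluded for the gonad count. Where the real count was 0, every split reaches it (35 of 35 in liver with and without liver effluent 1, 100 of 100 drawn for the difference between tissues), so these splits decide nothing about chance. The highest other count was 17 in liver on all arrays, 54 without liver effluent 1 and 29 for the difference. Between tissues 1 of 35 splits, the real one with 9642, reached its count, and the highest other called 7. Each other split put both tissues in each group, which widens the spread and lowers its count. A share of 1 in 35 is the smallest these splits can give, so chance is unlikely but not excluded. The highest other splits of the effluent comparisons followed position on the slide, positions 1 and 4 against 2 and 3 in gonad and 1 and 3 against 2 and 4 in liver. These were the highest of many splits, the position contrast was not the same in both tissues, and its cause was not tested. With position as a block, limma called 0 probes in gonad and 0 in liver, and 415 and 736 had an unadjusted p under 0.05.

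Probes made from clones of a gonad library were higher in gonad in 25 of 95 cases (26.3%), against 32.4% of 15264 other probes (two-sided Fisher's exact p = 0.227), which decided nothing. Of 393 probe pairs with and without the ending minus that were both tested between tissues, 131 were both called, 29 of them in opposite directions. Pairs of probes of one contig cluster had effects that correlated across 1629 clusters with r of 0.301 in gonad and across 1553 clusters with 0.536 between tissues.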
